A study of Mus musculus with 12 samples.

How the data were processed

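Liver RNA of 12 male C57BL/6J mice was hybridised to 12 Affymetrix arrays, 1 array per mouse. The labels name each array by diet, weeks on the diet and a biological replicate number, which gave 4 groups of 3 mice. The table deposited by the authors holds 1 signal per probe set and array, an intensity on a linear scale that, per the submitters' processing notes, was made with MAS5. The MAS5 version, its settings and the scaling target are not given in the sources used here. The trimmed mean of the signal, with 2% of the values left out at each end, was 499.9 on each array, so the deposited values had already been scaled to a common mean. Such scaling makes levels relative to the other transcripts of the same array. The median signal lay between 189.8 and 233.3. For arrays of this kind the number of arrays limits the precision.

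The table holds 22690 probe sets, of which 64 Affymetrix control probe sets were left out. Gene symbols came from a table of the platform's annotation: 20380 probe sets had 1 symbol, 691 had several and 1555 had none, and genes were named only from probe sets with 1 symbol. Through their Entrez identifiers 20351 probe sets matched a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names alone, and no coordinates are given because the build behind the array was not matched.

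Signals were analysed as log2(signal + 21), where the offset of 21 is 10% of the median signal of 213.1. Fold changes are on this scale and understate the change of genes with low signals. The 60% of probe sets with the highest mean over all arrays were tested, which left 13576 of 22626. A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (8 residual and 5.72 prior degrees of freedom). The contrasts were the effect of diet at 6 weeks, at 10 weeks and averaged over both times, the difference of the diet effect between times, and the effect of time on each diet. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Errors of log2 differences are standard errors of this model, and errors of signals are SD over 3 mice.

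Gene lists, 28 for pathways and 12 for cell types, were written from general knowledge. For 8475 genes the probe set with the highest mean stood for the gene, and 37 of the 40 lists had the 5 measured members needed for a test. Lists were tested with camera in limma, which compares a list with all other genes, at its preset correlation of 0.01 between genes. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, were run beside it. For the averaged diet effect an exact permutation test moved the diet labels of mice within each time, over 400 assignments, with a smallest two-sided p of 0.005. The likeness of the diet effects at both times was measured as a correlation across probe sets, which are not independent, with an exact one-sided permutation test over the same assignments.

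The genes named in the text followed a rule. Among genes past the threshold whose diet groups did not overlap, the 10 largest rises and 10 largest falls of each comparison were taken. For the averaged effect the direction had to be the same at both times, and for the difference between times no rule on overlap was applied. Where fewer than 5 genes of a direction passed, the list was filled to 5 by the smallest unadjusted p, and these are given as not past the threshold. In each gene list, members past the threshold were taken, up to 6, and otherwise up to 3 with the smallest p, given as values. Groups, tests, filter, offset, gene lists, this rule and the alternatives were fixed before the data were examined, apart from those named in the closing part as chosen later. The list test of the effect of time on garlic, fry and the permutation test of lists were also added after seeing the data.

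The model was tested on simulated data with the spread of the real arrays, in 10 simulations of 13576 probe sets of which 200 were changed. For the effect at 6 weeks it recovered 12.7% of 1.5-fold, 46.9% of 2-fold and 89.4% of 4-fold changes. The shares were 10.3%, 45.4% and 87.1% at 10 weeks and 35.7%, 74.9% and 96.2% for the averaged effect. False calls made up 5.9%, 4.9% and 5.2% of the calls of these 3 comparisons. In 10 simulations without any change, the 6 comparisons gave 6 false calls in all. Values were drawn from normal distributions, independently for each probe set and array, without correlated genes or shared cages. The shares in the real data may therefore differ.

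Alternatives were other offsets (2 and 107), no filter or the upper 40%, quantile normalization, median centring, no variance trend, array weights, 1 probe set per gene, a model on only the arrays compared, the replicate number as a block, a threshold of 0.10 and leaving out each array in turn. Added after seeing the data were 2 covariates, the mean of the acinar list and the ratio of 3' to 5' beta-actin signals, a sign of RNA quality, and leaving out the 5 arrays with a Cela2a signal over 1000. Per the series' design text each diet was housed in 2 cages, so mice of a diet shared cages and no cage held both diets. P-values, standard errors and permutations treat the mice as independent. Any effect of a cage could not be told apart from that of diet. Neither the cage nor the hour of death of each mouse is in the labels. Cages may thus have differed between the times as well, or have held mice of both times. Any difference in cages or processing between the 6-week and 10-week arrays could not be told apart from time. Such a difference in cages would also enter the difference of the diet effect between times.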

Results

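The data are liver transcript signals of 12 male mice of the inbred strain C57BL/6J, 8 weeks old at the start, that ate a purified diet with either 4% cellulose, a fibre used as the control, or 4% freeze-dried raw garlic powder. Livers were taken after 6 or 10 weeks, so that 4 groups of 3 mice were compared, with 1 array per mouse. The number of arrays limits the precision. Across all arrays albumin, the main plasma protein made by hepatocytes, had signals between 36270 and 49760. Pearson correlations of arrays, taken across probe sets, ran from 0.913 to 0.949 within groups and from 0.908 to 0.958 between groups. Transcripts of pancreatic acinar cells, which make digestive enzymes, were high in 5 arrays. Cela2a, a pancreatic elastase, had a signal of 2550 in cellulose replicate 1 at 6 weeks, 5180 and 9482 in garlic replicates 1 and 2 at 6 weeks, and 6092 and 1898 in garlic replicates 2 and 3 at 10 weeks. In the other 7 arrays it was at most 238.3.

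How liver transcripts differed between garlic and cellulose at 6 weeks was tested on 3 mice per diet. Alas1, the rate-limiting enzyme of heme synthesis in the liver, rose 2.75-fold on garlic (log2 1.46 ± 0.19, limma, adjusted p = 0.0249), from a signal of 6042 ± 998 to 16590 ± 2570. Tff2, a secreted trefoil peptide of mucous epithelia, rose 4.43-fold (log2 2.15 ± 0.32, adjusted p = 0.0476), from 57.5 ± 8.21 to 338.2 ± 111. For each of these genes all 3 garlic mice lay above all 3 cellulose mice. Tff2 also belongs to a list of skeletal muscle, gallbladder and gut transcripts, of which 3 of 8 were higher on garlic (mean -0.04, while camera pointed to higher values, adjusted p = 0.483). That mean changed sign with single arrays: it was 0.36 without cellulose replicate 3, 0.08 and 0.06 without garlic replicates 2 and 3, and -0.30, -0.17 and -0.25 without cellulose replicates 1 and 2 and garlic replicate 1. A probe set of Nfatc2, a transcription factor of activated T cells, fell 3.55-fold (log2 -1.83 ± 0.25, adjusted p = 0.033), from 344.3 ± 49 to 81.57 ± 11.5. It lay outside the rule for named genes and was chosen after its values were seen, and another Nfatc2 probe set, which had the highest mean over all arrays, differed by log2 0.14 ± 0.25 (adjusted p = 0.93). A second Alas1 probe set gave log2 1.23 ± 0.38 (limma, adjusted p = 0.447). Clock genes also differed between the diets at 6 weeks, as the closing part shows. So different hours of death, which are not in the labels, cannot be told apart from diet for these genes.

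Further genes with the smallest p at 6 weeks did not pass. Garlic minus cellulose was log2 0.86 ± 0.14 for Upp2, a uridine phosphorylase, and 1.20 ± 0.24 for Cdh1, the adhesion protein E-cadherin (adjusted p = 0.062 and 0.164). It was -1.40 ± 0.24 for Clpx, a mitochondrial chaperone of the Clp protease, and -1.23 ± 0.21 for Apoa4, an apolipoprotein of triglyceride-rich particles (adjusted p = 0.099 for both). The chemokine gene Ccl5 differed by -2.55 ± 0.50, the tight junction gene Cldn2 by -0.78 ± 0.15 (adjusted p = 0.164 for both) and the magnesium transporter gene Slc41a2 by -2.27 ± 0.40 (adjusted p = 0.122). Of 13576 probe sets limma called 3, 2 higher and 1 lower, and 1087 had an unadjusted p under 0.05, where chance gives 679. The groups did not overlap for 1987 probe sets, or 14.6%, where chance gives 10%. The count of 3 became 18 without cellulose replicate 3 and 0 without cellulose replicate 1 or 2 or garlic replicate 1, 2 or 3. With the acinar mean as a covariate, chosen after seeing the data, the 1 call was Apoa4 (log2 -1.49), and Alas1 (1.51), Tff2 (1.93) and Nfatc2 (-1.87) did not pass. Leaving out the arrays high in acinar transcripts, also chosen later, left 1 garlic and 2 cellulose mice, with the lone mouse assumed to vary like the other groups. Then 0 probe sets were called, at log2 1.77 for Alas1, 1.58 for Tff2 and -1.95 for Nfatc2. Over all alternatives Alas1 passed in 9 of 20, Tff2 in 5 of 19 and Nfatc2 in 6 of 18.

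**Figure D1:**
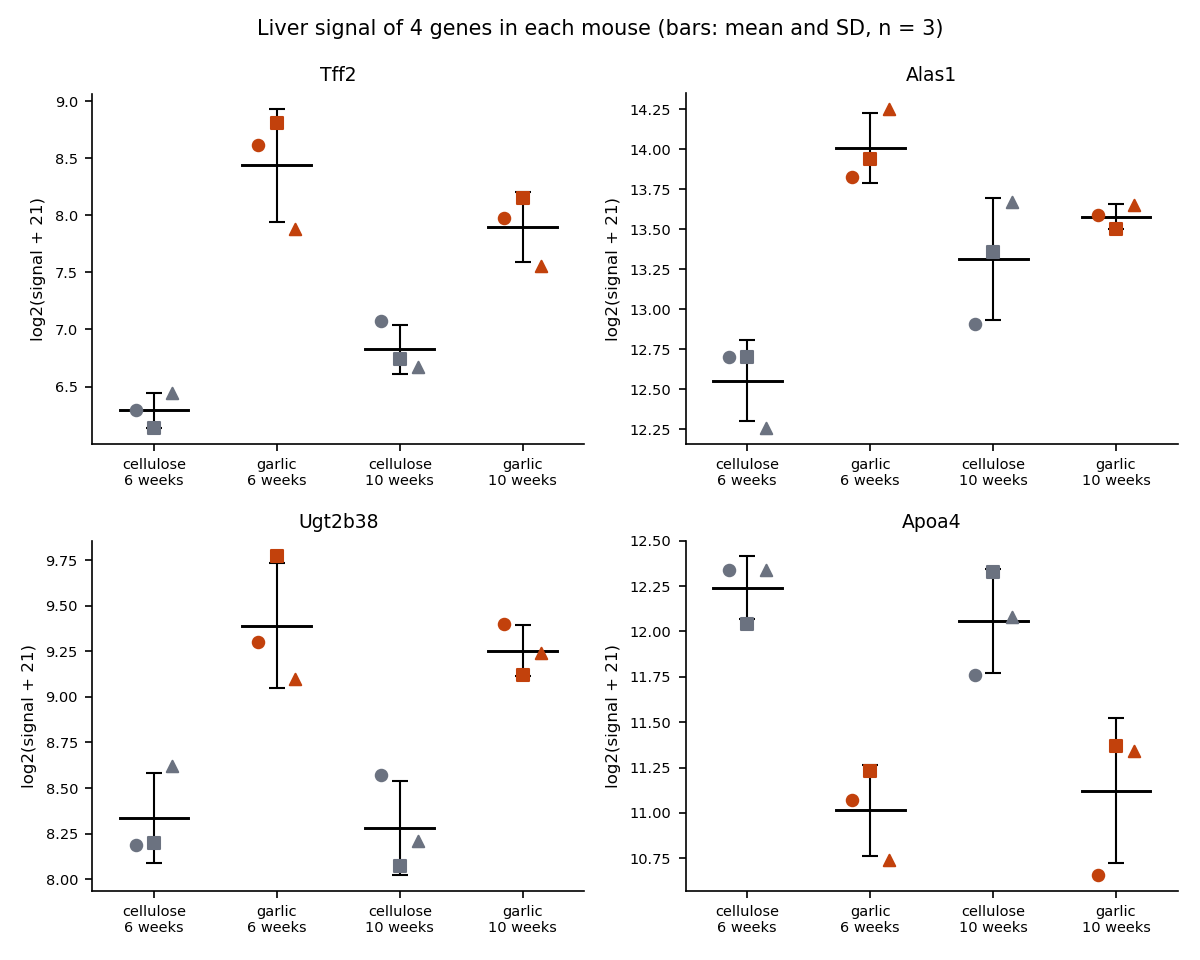
Signal of Tff2, Alas1, Ugt2b38 and Apoa4 in each mouse, as log2(signal + 21), by diet (grey cellulose, orange garlic) and weeks on the diet; symbols mark the replicate number, and lines with bars are mean and SD of 3 mice. Tff2 and Ugt2b38 were higher and Apoa4 lower in each of the 6 garlic mice than in any of the 6 cellulose mice, while mean Alas1 signals were 6042 and 16590 at 6 weeks and 10370 and 12240 at 10 weeks.

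At the level of gene lists, acute phase genes, which encode plasma proteins that the liver secretes in inflammation, fell on garlic at 6 weeks. Of 28 measured members 25 were lower, with a mean log2 difference of -0.90 (camera, adjusted p = 5.04e-11; adjusted p = 0.561 with an estimated correlation). Adjusted over the list alone 9 members passed, among them Crp (-0.56 ± 0.15), Hp (-0.59 ± 0.18) and Steap4 (-1.49 ± 0.37), against 0 in limma over all genes, and 15 had an unadjusted p under 0.05. Genes of the ER stress response, which handle unfolded secretory proteins, fell with a mean of -0.40, 22 of 26 lower, with Syvn1 at -0.84 ± 0.27 and Dnajc3 at -0.60 ± 0.21 (adjusted p = 6.79e-08; adjusted p = 0.561 with an estimated correlation). Proteasome genes fell as a list by a smaller mean of -0.14, 25 of 31 lower (adjusted p = 0.000746; adjusted p = 0.561 with an estimated correlation). Markers of Kupffer cells and macrophages, the resident phagocytes, fell with 13 of 13 lower and a mean of -0.64, with Mpeg1 at -0.97 ± 0.37 and Cd68 at -0.89 ± 0.40 (adjusted p = 4.85e-05; adjusted p = 0.604 with an estimated correlation). The acinar list rose in the same mice, 10 of 10 higher with a mean of 2.17, with Ctrb1, a chymotrypsinogen, at 2.53 ± 1.14 (adjusted p = 2e-04; adjusted p = 0.604 with an estimated correlation).

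Genes of fatty acid and triglyceride synthesis rose at 6 weeks, 19 of 23 higher with a mean of 0.27, with Dgat2 at 0.47 ± 0.14 and Fads2 at 0.46 ± 0.20 (camera, adjusted p = 0.00303; adjusted p = 0.561 with an estimated correlation). Lipoprotein and lipid transport genes fell, 17 of 23 lower with a mean of -0.20 (adjusted p = 0.0126; adjusted p = 0.561 with an estimated correlation). Adjusted over the list alone 2 passed, Apoa4 and the fatty acid uptake gene Cd36 (-1.39 ± 0.38), against 0 in limma over all genes, where 2 had an unadjusted p under 0.05. Antigen presentation genes of MHC class II fell, 7 of 7 lower, mean -0.71, with H2-Ab1 at -1.08 ± 0.41 (adjusted p = 0.00303; adjusted p = 0.604 with an estimated correlation). Interferon response genes fell, 16 of 23 lower, mean -0.18, with Ifit1 at -0.64 ± 0.21 (adjusted p = 0.0126; adjusted p = 0.604 with an estimated correlation). In the ER stress, proteasome, macrophage, acinar, fatty acid synthesis, MHC class II and interferon lists 0 members passed in limma, adjusted over the list alone or over all genes, with 10, 3, 3, 3, 4, 1 and 1 at an unadjusted p under 0.05. In all camera called 9 of 37 lists, 2 higher and 7 lower. The estimated correlation and fry called 0, with 4 lists at an unadjusted p under 0.05 in fry. The calls of acute phase, ER stress and proteasome genes were kept without each of the 6 arrays. Without cellulose replicate 2 the adjusted p was 0.0613 for macrophage markers, 0.247 for fatty acid synthesis, 0.0911 for MHC class II, 0.712 for interferon and 0.0613 for lipoproteins. Without garlic replicate 2 it was 0.184 for the acinar list, 0.0885 for fatty acid synthesis, 0.0545 for MHC class II and 0.0767 for interferon. The lipoprotein call was also lost without garlic replicate 1 (0.0713) or 3 (0.0805). The number of lists called was 4 without cellulose replicate 2, 16 without cellulose replicate 3 and 5 without garlic replicate 2, and it was 5 without the arrays high in acinar transcripts, which left 1 garlic against 2 cellulose mice and an acute phase mean of -0.57. The calls lost there were those of fatty acid synthesis, MHC class II, interferon and acinar genes. Quantile normalization and the actin covariate ended the lipoprotein call, and array weights and the acinar covariate the acinar call. As that covariate is the mean of the acinar list itself, the loss of the acinar call with it was fixed in advance. Leaving out cellulose replicate 2 gave means of -0.29 for macrophage markers, 0.12 for fatty acid synthesis, -0.39 for MHC class II and -0.02 for interferon genes. Without cellulose replicate 3 they were -1.01 for macrophage markers, -1.08 for MHC class II and -0.36 for interferon genes. The acinar mean was 1.23 without garlic replicate 2 and 3.57 without garlic replicate 3.

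**Figure D2:**
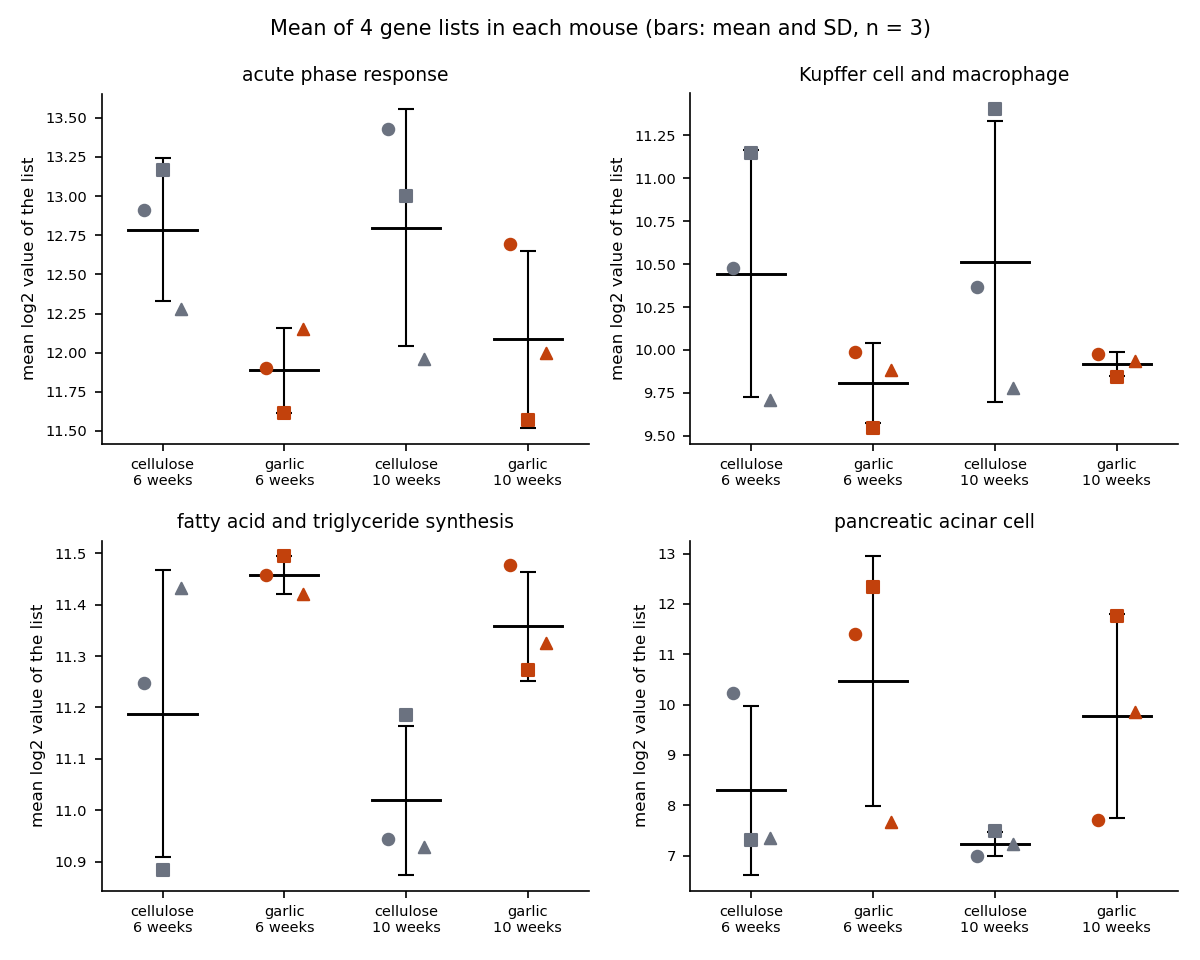
Mean log2(signal + 21) over the measured genes of 4 lists (acute phase, Kupffer cell and macrophage, fatty acid and triglyceride synthesis, pancreatic acinar) in each mouse, by diet and weeks, with symbols for the replicate number and lines with bars for mean and SD of 3 mice. Acinar means lay between 9.85 and 12.34 in 5 mice and between 7.00 and 7.71 in the other 7.

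After 10 weeks on the diets, no gene passed the test between garlic and cellulose, with 3 mice per diet. Among the named genes were glutathione S-transferases, whose products conjugate electrophiles: Gsta4 had signals of 252.2 ± 138 on cellulose and 890 ± 274 on garlic (log2 1.84 ± 0.34), and Gsta2 395.3 ± 217 and 1320 ± 304 (log2 1.84 ± 0.39), with adjusted p = 0.224 and 0.251. Tigd5 differed by 0.93 ± 0.16 (adjusted p = 0.224), Flna, an actin-binding protein, by 1.44 ± 0.29, and Slc25a22, a mitochondrial glutamate carrier, by 0.77 ± 0.16 (adjusted p = 0.251 for both). Slc22a7, an organic anion transporter of hepatocytes, had 2186 ± 426 on cellulose and 830.9 ± 225 on garlic (log2 -1.39 ± 0.20, adjusted p = 0.112). Lower values were also measured for the tetraspanin gene Cd81 (-0.70 ± 0.11, adjusted p = 0.185), the acute phase gene Orm3 (-3.51 ± 0.63) and the acetyltransferase gene Nat8 (-0.80 ± 0.15, adjusted p = 0.224 for both), and the plasma glycoprotein gene Hrg (-0.60 ± 0.12, adjusted p = 0.251). Limma called 0 of 13576 probe sets, with 1061 at an unadjusted p under 0.05 against 679 by chance and a lowest adjusted p of 0.112. The groups did not overlap for 1593 probe sets (11.7%, chance 10%). The count was 63 without cellulose replicate 3 and 1 without garlic replicate 2.

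Among the lists at 10 weeks, acute phase genes fell again, 26 of 28 lower with a mean of -0.71, with Apcs, serum amyloid P, at -1.77 ± 0.54 (camera, adjusted p = 1.17e-06; adjusted p = 0.911 with an estimated correlation). Adjusted over the list alone Orm3 was the 1 member that passed, against 0 in limma over all genes, where 11 had an unadjusted p under 0.05. Fatty acid and triglyceride synthesis genes rose, 16 of 23 higher with a mean of 0.34 (adjusted p = 0.00847; adjusted p = 0.911 with an estimated correlation). Of these, 5 passed adjusted over the list alone, among them the desaturase gene Fads2 (0.82 ± 0.20), the elongase gene Elovl5 (0.74 ± 0.19) and malic enzyme, Me1 (0.98 ± 0.29), against 0 in limma over all genes, where 8 were higher and 1 lower at an unadjusted p under 0.05. Ribosomal protein genes were lower on garlic than on cellulose in 24 of 27, mean -0.17, with Rps2 at -0.44 ± 0.12 (camera, adjusted p = 4.51e-05, and 0.911 with an estimated correlation). Kupffer cell and macrophage markers fell, 12 of 13 lower, mean -0.60, with Vsig4 at -1.22 ± 0.51 and C1qb at -0.74 ± 0.34 (adjusted p = 0.000304; adjusted p = 0.933 with an estimated correlation). The acinar list rose in the same mice, 10 of 10 higher, mean 2.53 (adjusted p = 4.51e-05; adjusted p = 0.911 with an estimated correlation), and its member Ctrb1 (4.01 ± 1.14) passed adjusted over the list alone, against 0 in limma over all genes, where 3 had an unadjusted p under 0.05. Without cellulose replicate 2 the adjusted p of the macrophage markers was 0.402 (mean -0.15), and without garlic replicate 2 that of the acinar list was 0.06 (mean 1.54). The acute phase mean was -0.39 without cellulose replicate 1, -1.13 without cellulose replicate 3 and -0.45 without garlic replicate 2. The ribosomal mean was -0.11 without cellulose replicate 2 and -0.28 without cellulose replicate 3, where the macrophage mean was -0.97.

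Phase II conjugation enzymes attach glutathione, sulfate or glucuronic acid. At 10 weeks 21 of 30 were higher on garlic than on cellulose, with a mean of 0.21 (camera, adjusted p = 0.0368, and 0.911 with an estimated correlation). Among them was Gstm6 (0.76 ± 0.17). Adjusted over the list alone Gstm6 was the 1 member past the threshold, against 0 in limma over all genes, where 7 had an unadjusted p under 0.05. For targets of NRF2, a regulator of antioxidant genes, 24 of 35 were higher with a mean of 0.22, and the list was not called (adjusted p = 0.0552). Its mean was 0.13 without cellulose replicate 1 (adjusted p = 0.441), and it was called without cellulose replicate 2 (0.32, adjusted p = 0.0355) or 3 (0.21, adjusted p = 0.0053). Of these, Gsta4 and Gsta2 passed adjusted over the list alone, against 0 in limma over all genes, where 6 had an unadjusted p under 0.05. Fatty acid oxidation genes and targets of PPAR alpha rose, 21 of 28 higher, mean 0.33, with Cyp4a14 at 2.56 ± 0.91 and Ehhadh at 0.92 ± 0.35 (adjusted p = 0.0368; adjusted p = 0.983 with an estimated correlation). Oxidative phosphorylation genes rose by a mean of 0.12, 37 of 46 higher, with Ndufs1 at 0.45 ± 0.17 (adjusted p = 0.0368; adjusted p = 0.983 with an estimated correlation). Extracellular matrix genes fell with a mean of -0.20, 10 of 18 lower, with Bgn at -0.56 ± 0.18 (adjusted p = 0.0484; adjusted p = 0.983 with an estimated correlation). Neutrophil markers fell with 6 of 8 lower and a mean of -0.63 (camera, adjusted p = 0.0484, and 0.933 with an estimated correlation). Among them was Lcn2 at -2.73 ± 1.23, which is also on the acute phase list. In the PPAR alpha, oxidative phosphorylation, matrix, neutrophil, ribosomal and macrophage lists 0 members passed in limma, adjusted over the list alone or over all genes, with 3, 2, 1, 1, 4 and 3 at an unadjusted p under 0.05. Camera called 10 of 37 lists, 5 higher and 5 lower. The estimated correlation and fry called 0, with 1 list at an unadjusted p under 0.05 in fry. Without cellulose replicate 1 the adjusted p was 0.427 for phase II enzymes, 0.633 for PPAR alpha targets, 0.0981 for matrix and 0.0575 for neutrophil genes, and 6 lists were called. Without cellulose replicate 2 it was 0.104, 0.965, 0.55 and 0.498 for these lists and 0.965 for oxidative phosphorylation. Without garlic replicate 2, which left 5 lists, the values were 0.06, 0.305, 0.266, 0.111 and 0.266 in the same order. Leaving out garlic replicate 1 gave 0.103 for matrix genes, and leaving out garlic replicate 3 gave 0.141 for phase II, 0.132 for PPAR alpha and 0.219 for neutrophil genes. The number of lists was 15 without cellulose replicate 3, and it was 3 with the acinar covariate, namely acute phase, ribosomal and macrophage genes. A model on only the arrays compared ended the calls of phase II, PPAR alpha, oxidative phosphorylation, matrix and neutrophil genes. Of these, the actin covariate ended all but phase II, array weights and having no filter ended oxidative phosphorylation and neutrophil genes, and median centring ended oxidative phosphorylation. Matrix genes also lost their call with array weights, phase II enzymes without a filter, and matrix and neutrophil genes with the upper 40% and the offset of 2. Leaving out the arrays high in acinar transcripts left 1 garlic against 3 cellulose mice, and 1 list, ribosomal proteins, was called. The means were then -0.54 for macrophage markers and 0.46 for fatty acid synthesis, and -0.11 for acute phase, -0.13 for neutrophil and 0.15 for PPAR alpha genes. The PPAR alpha mean was 0.14, 0.15 and 0.69 without cellulose replicates 1, 2 and 3, and that of phase II enzymes was 0.11 without cellulose replicate 1. Without cellulose replicates 2 and 3 in turn the means were 0.04 and 0.19 for oxidative phosphorylation, -0.05 and -0.37 for matrix, and -0.31 and -1.07 for neutrophil genes. Matrix genes had a mean of -0.13 without garlic replicate 2.

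Averaging the diet effect over both times compared 6 garlic with 6 cellulose mice. Tff2 rose 3.05-fold (log2 1.61 ± 0.23, limma, adjusted p = 0.0378), with signals of 93.37 ± 17.6 on cellulose and 221 ± 48.9 on garlic at 10 weeks. Ugt2b38, which adds glucuronic acid to small molecules, rose 2.02-fold (log2 1.01 ± 0.15, adjusted p = 0.0438), from 305.6 ± 58.3 to 663.7 ± 168 at 6 weeks and from 293.5 ± 57.8 to 590.6 ± 60.2 at 10 weeks. Alas1 rose 1.82-fold (log2 0.86 ± 0.13, adjusted p = 0.0438), though at 10 weeks its signals were 10370 ± 2640 and 12240 ± 612. Apoa4 fell 2.11-fold (log2 -1.08 ± 0.15, adjusted p = 0.0378), from 4840 ± 556 to 2070 ± 356 at 6 weeks and from 4291 ± 844 to 2262 ± 579 at 10 weeks, and its other probe set gave -0.80 ± 0.16 (adjusted p = 0.113). Values of Tff2, Ugt2b38 and Apoa4 did not overlap between the 6 mice of each diet. Genes not past the threshold included Fgl1, a secreted fibrinogen-like protein (-1.62 ± 0.26, adjusted p = 0.058), Slc41a2 (-1.74 ± 0.28, 0.0636), Orm3 (-2.64 ± 0.44, 0.0705), Acnat2, related to the bile acid conjugating enzyme (-2.29 ± 0.39, 0.083), Cdh1 (0.89 ± 0.17) and Flna (1.09 ± 0.21, both adjusted p = 0.102).

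For the averaged effect limma called 4 of 13576 probe sets, 3 higher and 1 lower, and 1598 had an unadjusted p under 0.05, where chance gives 679. The count became 0 without cellulose replicate 1 or 2 or garlic replicate 1 or 2 at 6 weeks, or without cellulose replicate 2 or garlic replicate 1 or 2 at 10 weeks. It was 1 without garlic replicate 3 at 6 weeks, 31 without cellulose replicate 3 at 6 weeks and 124 without cellulose replicate 3 at 10 weeks. With the acinar mean as a covariate Apoa4 was the 1 probe set called (log2 -1.36, adjusted p = 0.0075, where the range over all 25 alternatives was 0.0075 to 0.374), and log2 was 0.92 for Alas1, 0.98 for Ugt2b38 and 1.37 for Tff2. Leaving out the arrays high in acinar transcripts left 1 garlic mouse at each time, against 2 and 3 cellulose mice, and 0 probe sets were called. Then log2 was -1.43 for Apoa4, 1.02 for Alas1, 0.90 for Ugt2b38 and 1.37 for Tff2. Over all alternatives Tff2 passed in 10 of 24, Apoa4 in 10 of 25, Ugt2b38 in 8 of 25 and Alas1 in 7 of 25.

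As lists, averaged over both times, acute phase genes fell in 26 of 28 members with a mean of -0.80 (camera, adjusted p = 7.97e-13; adjusted p = 0.665 with an estimated correlation). Adjusted over the list alone 17 members passed, among them Steap4 (-1.16 ± 0.26) and Apcs (-1.64 ± 0.38), against 0 in limma over all genes, where 18 had an unadjusted p under 0.05. Lcn2, lipocalin 2, which belongs to the acute phase and the neutrophil list, had signals of 13200 ± 10200 and 14300 ± 12600 on cellulose and 765.8 ± 535 and 1996 ± 2630 on garlic. Kupffer cell and macrophage markers fell in 13 of 13 with a mean of -0.62 (adjusted p = 1.28e-06; adjusted p = 0.694 with an estimated correlation). Of these, 4 passed adjusted over the list alone, Mpeg1 (-0.91 ± 0.26), Vsig4 (-1.16 ± 0.36), C1qb (-0.73 ± 0.24) and Cd68, against 0 in limma over all genes, where 7 had an unadjusted p under 0.05. ER stress genes fell in 23 of 26, mean -0.26, with Sdf2l1 at -0.49 ± 0.14 (adjusted p = 4.53e-06; adjusted p = 0.665 with an estimated correlation). Here 0 members passed in limma, adjusted over the list alone or over all genes, and 9 had an unadjusted p under 0.05. Fatty acid and triglyceride synthesis genes rose in 20 of 23, mean 0.30 (adjusted p = 0.000278; adjusted p = 0.665 with an estimated correlation), and 6 members passed adjusted over the list alone, among them Fads2 (0.64 ± 0.14), Me1 (0.78 ± 0.20) and Elovl6 (0.47 ± 0.13), against 0 in limma over all genes, where 8 had an unadjusted p under 0.05. Lipoprotein and lipid transport genes fell in 18 of 23, mean -0.15, with Apoa4 past the threshold (adjusted p = 0.0154; adjusted p = 0.665 with an estimated correlation). The acinar list rose in the same mice in 10 of 10, mean 2.35, with Prss2, a trypsinogen, at 2.19 ± 0.69 (adjusted p = 1.28e-06; adjusted p = 0.665 with an estimated correlation). All 10 acinar genes passed adjusted over the list alone, against 0 in limma over all genes, where 10 had an unadjusted p under 0.05. The calls of these 6 lists were kept without each of the 12 arrays, with a macrophage mean of -0.40 without cellulose replicate 2 at 10 weeks. Without the arrays high in acinar transcripts the acute phase mean was -0.34 and the acinar call was lost. The lipoprotein call was lost after quantile normalization. Hepatocyte markers differed by a mean of -0.02 with a median of the opposite sign (0.04), and endothelial markers by 0.03 (adjusted p = 0.692 and 0.722). Without single arrays these means ran from -0.06 to 0.01 and from -0.01 to 0.08, with changes of sign without cellulose replicate 1 or garlic replicate 3 at 10 weeks for hepatocyte and without cellulose replicate 3 at 10 weeks for endothelial markers.

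Of the 13 lists called for the averaged effect, 3 higher and 10 lower, 7 others lost their call without single arrays. Proteasome genes fell in 26 of 31, mean -0.08, with Psmc5 at -0.52 ± 0.11 (adjusted p = 0.0119; adjusted p = 0.665 with an estimated correlation), and the adjusted p was 0.0694 without cellulose replicate 3 at 10 weeks. Ribosomal protein genes fell in 22 of 27, mean -0.07 (0.0154; adjusted p = 0.707 with an estimated correlation). Matrix genes fell in 11 of 18, mean -0.19 (0.0154), MHC class II genes in 6 of 7, mean -0.42, with Ctss at -0.65 ± 0.19 (0.0334), interferon genes in 15 of 23, mean -0.13 (0.0383), and neutrophil markers in 7 of 8, mean -0.64 (0.0383), each with adjusted p = 0.707 with an estimated correlation. Oxidative phosphorylation genes rose in 36 of 46, mean 0.09 (0.0383; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 1 member passed in each of the proteasome, MHC class II and neutrophil lists. These were Psmc5, Ctss and Lcn2, the last also on the acute phase list. In limma over all genes 0 of them passed, and 2, 1 and 1 members of these lists had an unadjusted p under 0.05. In the ribosomal, matrix, interferon and oxidative phosphorylation lists 0 passed in limma by either adjustment, with 3, 5, 4 and 5 at an unadjusted p under 0.05. Without cellulose replicate 2 at 6 weeks the adjusted p was 0.0705 for ribosomal and matrix genes, 0.151 for MHC class II, 0.394 for interferon, 0.102 for neutrophil and 0.251 for oxidative phosphorylation genes. Without cellulose replicate 2 at 10 weeks it was 0.166, 0.21, 0.376, 0.21, 0.354 and 0.598 in the same order. Leaving out garlic replicate 2 at 6 weeks gave 0.11 for matrix and MHC class II, 0.108 for interferon, 0.255 for neutrophil and 0.407 for oxidative phosphorylation genes. Each of these 3 arrays left 8 lists. Cellulose replicate 1 at 6 weeks, when left out, gave 0.0672 for MHC class II and interferon, 0.137 for neutrophil and 0.0704 for oxidative phosphorylation genes, and cellulose replicate 1 at 10 weeks gave 0.0943 for ribosomal genes. Garlic replicate 3 at 6 weeks gave 0.0593 for interferon, and at 10 weeks garlic replicate 1 gave 0.0786 for MHC class II and garlic replicate 3 gave 0.109 for neutrophil genes. Garlic replicate 2 at 10 weeks gave 0.105 for interferon, 0.0704 for matrix, 0.0651 for neutrophil and 0.203 for oxidative phosphorylation genes. Leaving out cellulose replicate 2 at 6 weeks gave means of -0.26 for MHC class II and -0.05 for interferon genes, and without cellulose replicate 3 at 6 weeks the interferon mean was -0.22. The averaged means without cellulose replicate 2 at 10 weeks were -0.19 for MHC class II, -0.04 for ribosomal, -0.11 for matrix and 0.05 for oxidative phosphorylation genes. The ribosomal mean was -0.12 without cellulose replicate 3 at 10 weeks. With the acinar covariate 7 lists were called, and 5 without the arrays high in acinar transcripts, which left 1 garlic mouse at each time and means of -0.15 for neutrophil and -0.40 for MHC class II genes. The acinar call had to be lost with the covariate, which is the mean of that list. The covariate also ended the calls of the MHC class II, interferon, matrix, neutrophil and oxidative phosphorylation lists. Leaving out the arrays ended the acinar call, the calls of these lists and the proteasome and ribosomal calls. Quantile normalization ended the interferon, proteasome and ribosomal calls, the last at a mean of -0.01. Array weights ended MHC class II, interferon and oxidative phosphorylation, having no filter ended neutrophil and oxidative phosphorylation, the upper 40% interferon and neutrophil, the offset of 107 interferon, and median centring oxidative phosphorylation. The estimated correlation, fry and the exact permutation test, adjusted over the lists, called 0 of 37 lists, with 6 at an unadjusted p under 0.05 in fry and 4 in the permutation test. Those 4 were fatty acid synthesis and lipoproteins (p = 0.01 for both, two-sided exact permutation, adjusted 0.185) and acute phase and acinar genes (p = 0.03 for both, adjusted 0.277).

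Whether the diet effects at both times resembled each other was asked across probe sets, with different mice on all sides. Mice of a diet may have shared a cage across times, which the labels do not give. Pearson's r of the effects at 6 and 10 weeks was 0.37 and Spearman's rho was 0.26, across 13576 probe sets that are not independent (one-sided exact permutation p = 0.005, the observed r being the largest of the 400 assignments). The sign was the same for 59.2% of probe sets. An unadjusted p under 0.05 at both times was found for 167 probe sets, where independent lists would share 85, and 150 of these had the same direction. Of those, 61 were higher on garlic and 89 were lower, against 20 and 22.4 for independent lists. Orm3, Slc41a2, Apoa4, Cdh1 and Flna had the same sign at both times. Without the arrays high in acinar transcripts r was 0.22 (exact permutation p = 0.167, range over the alternatives 0.005 to 0.167). It was also 0.22 without a filter (exact permutation p = 0.01). Without the acinar arrays 1 garlic array was left at each time and 12 assignments, whose smallest p is 0.0833, so this test could not pass. With acute phase, macrophage and acinar genes left out it was 0.29 (exact permutation p = 0.015). Leaving out these arrays or these genes was chosen after seeing the data.

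**Figure D3:**
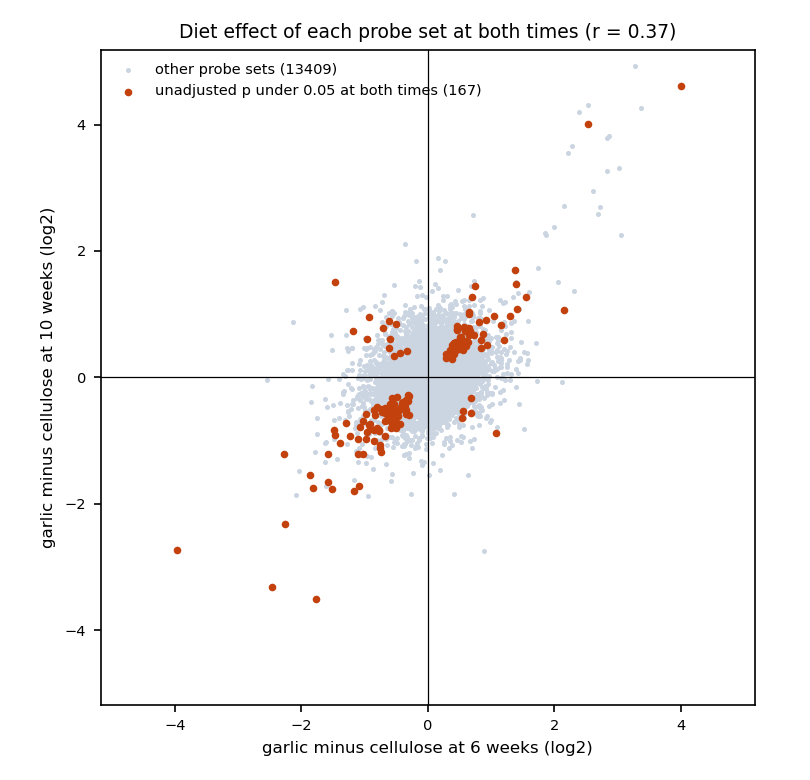
Garlic minus cellulose at 10 weeks against that at 6 weeks, both as log2 differences, for 13576 probe sets; orange points are the 167 with an unadjusted p under 0.05 at both times and grey points are the rest. Most orange points lie in the lower left and upper right, 89 lower and 61 higher at both times, and r over all points was 0.37.

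The difference of the diet effect between times, 10 weeks minus 6 weeks, was tested directly. The named genes did not pass: Junb, an immediate early transcription factor, had a difference of log2 2.98 ± 0.57 (adjusted p = 0.595), Nfil3, a repressor tied to the circadian clock, 1.92 ± 0.39 (0.649), Slc22a7 -1.29 ± 0.29 and Alas1 -1.19 ± 0.26 (0.68 for both), Clpx 1.38 ± 0.34 (0.967) and Upp2 -0.76 ± 0.19 (1). The called probe sets of Nfatc2 (1.70 ± 0.36, adjusted p = 0.649) and Tff2 (-1.07 ± 0.45, adjusted p = 1) did not pass either, so their presence among the calls at 6 weeks was not shown to differ from 10 weeks. As lists, targets of NRF2 (mean 0.33, 24 of 35 higher), phase II enzymes (mean 0.24, 23 of 30 higher) and ER stress genes (mean 0.27, 20 of 26 higher) had a higher diet effect at 10 weeks, and ribosomal protein genes a lower diet effect (mean -0.21, 25 of 27 lower). In this order camera gave adjusted p = 0.0225, 0.0181, 0.0181 and 0.00201, and each list had adjusted p = 0.908 with an estimated correlation. In these lists 0 members passed in limma, adjusted over the list alone or over all genes, with 5, 1, 1 and 2 at an unadjusted p under 0.05. Named members were Gsta2 (2.02 ± 0.55) and Gsta4 (1.57 ± 0.47), Syvn1 (0.77), Rps2 (-0.53 ± 0.17) and Rpl35 (-0.52 ± 0.21). Mean log2 values of phase II enzymes at 6 and 10 weeks were 11.427 and 11.15 on cellulose and 11.406 and 11.364 on garlic. ER stress genes had 10.961 and 10.625 against 10.565 and 10.501, and ribosomal protein genes 12.375 and 12.611 against 12.414 and 12.436. These lists thus moved more on cellulose than on garlic. NRF2 targets had 10.856 and 10.681 on cellulose and 10.742 and 10.901 on garlic. For lists called at 1 time alone the difference was not called for MHC class II and proteasome genes (adjusted p = 0.13), PPAR alpha targets (0.193), interferon (0.367), oxidative phosphorylation (0.488), lipoproteins (0.553), neutrophil (0.723) and matrix genes (0.891). Limma called 0 of 13576 probe sets, with 536 at an unadjusted p under 0.05 against 679 by chance, and 7 were called without cellulose replicate 3 at 10 weeks. The estimated correlation, fry and the permutation test called 0 lists, and fry had 0 lists at an unadjusted p under 0.05. For the difference an averaged diet effect enters the permuted values, so the permutation test cannot decide here.

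The list calls for the difference were lost without single arrays. Without cellulose replicate 1 at 6 weeks the adjusted p was 0.0594 for NRF2 targets and for phase II enzymes, and without cellulose replicate 2 at 6 weeks it was 0.127 for NRF2 targets and 0.25 for ER stress genes. Without garlic replicate 1 at 6 weeks it was 0.0861 for NRF2, phase II and ER stress genes, and without garlic replicate 3 at 6 weeks 0.0694 for NRF2 and phase II and 0.0504 for ER stress genes. Leaving out cellulose replicate 1 at 10 weeks gave 0.183 for NRF2, 0.188 for phase II and 0.0504 for ribosomal protein genes. ER stress genes had 0.531 without cellulose replicate 2 and 0.108 without garlic replicate 2 at 10 weeks. Garlic replicate 3 at 10 weeks, left out, gave 0.0911 for NRF2 and 0.084 for phase II genes. The number of lists was 1 without garlic replicate 1 or 3 at 6 weeks, 2 without cellulose replicate 1 at either time or garlic replicate 3 at 10 weeks, 10 without cellulose replicate 3 at 6 weeks, and 8 without cellulose replicate 2 or 3 at 10 weeks. The mean of phase II enzymes was 0.13 without cellulose replicate 1 at 10 weeks. That of ER stress genes was 0.16 without cellulose replicate 2 at 6 weeks, and 0.11 and 0.41 without cellulose replicates 2 and 3 at 10 weeks. That of ribosomal protein genes was -0.32 without cellulose replicate 3 at 10 weeks. The actin covariate ended the ER stress call. Leaving out the arrays high in acinar transcripts left 1 garlic mouse at each time, and camera called 0 lists. The means were then 0.41 for NRF2 targets, 0.27 for phase II, 0.29 for ER stress and -0.20 for ribosomal protein genes.

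Between 6 and 10 weeks on cellulose, no gene passed the test. Dbp, a transcription factor driven by the circadian clock, had signals of 292.6 ± 65.6 and 1342 ± 568 (log2 2.06 ± 0.29, adjusted p = 0.094), and Nr1d2, a clock repressor, differed by 0.94 ± 0.20 (adjusted p = 0.274). Later minus earlier was -1.44 ± 0.24 for Clpx, -2.76 ± 0.46 for the tubulin gene Tubb2a, -1.28 ± 0.22 for choline kinase, Chka (adjusted p = 0.112 for the 3), -1.60 ± 0.28 for Insig2, which holds sterol sensors in the ER (0.114) and -1.24 ± 0.22 for Gldc, which breaks down glycine (0.143). Alas1 differed by 0.76 ± 0.19 (0.492). The circadian clock list rose in 13 of 16, mean 0.39 (camera, adjusted p = 0.00405; adjusted p = 0.366 with an estimated correlation). Of these, Dbp, Nr1d2, Usp2 and Nfil3 passed adjusted over the list alone, 3 higher and 1 lower. Over all genes limma called 0 of them, and 4 had an unadjusted p under 0.05. Ribosomal protein genes rose in 27 of 27, mean 0.24, with Rps3 at 0.50 ± 0.14 (adjusted p = 3.02e-07; adjusted p = 0.52 with an estimated correlation). Phase II enzymes fell in 25 of 30, mean -0.28 (adjusted p = 2.91e-06; adjusted p = 0.259 with an estimated correlation). Of these, Gstm6 (-0.70 ± 0.17), Ugt2b1 (-0.62 ± 0.18) and Sult1d1 (-0.79 ± 0.21) passed adjusted over the list alone, against 0 in limma over all genes, where 9 had an unadjusted p under 0.05. ER stress genes fell in 22 of 26, mean -0.34, with Dnajb9 at -0.77 ± 0.23 (adjusted p = 1.1e-05; adjusted p = 0.52 with an estimated correlation). Genes of the urea cycle and amino acid catabolism fell in 18 of 25, mean -0.15, with Asl at -0.52 ± 0.15 (adjusted p = 0.00405; adjusted p = 0.52 with an estimated correlation). The phase II mean was -0.17 without replicate 1 at 10 weeks, and the ER stress mean was -0.22 without replicate 2 at 6 weeks and -0.17 without replicate 2 at 10 weeks. The clock list was called without each of the 6 cellulose arrays in turn (camera, highest adjusted p = 0.0435). Its call was lost in the fit without all arrays high in acinar transcripts, garlic arrays among them (mean 0.34). That fit left 2 cellulose mice at 6 weeks and 3 at 10 weeks. The actin covariate ended the urea cycle call.

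Oxidative phosphorylation genes also fell with time on cellulose, 36 of 46 lower, mean -0.11 (camera, adjusted p = 0.00405; adjusted p = 0.85 with an estimated correlation), as did proteasome genes, 24 of 31 lower, mean -0.09 (adjusted p = 0.0299; adjusted p = 0.673 with an estimated correlation). In the ribosomal, ER stress, urea cycle, oxidative phosphorylation and proteasome lists 0 members passed in limma, adjusted over the list alone or over all genes, with 6, 8, 2, 1 and 1 at an unadjusted p under 0.05. The acinar list was lower at 10 weeks in 10 of 10 members, mean -1.06, and was not called (adjusted p = 0.0835). This rests on replicate 1 at 6 weeks, without which the mean was -0.10 (adjusted p = 0.949), while it was called without replicate 2 (-1.56, adjusted p = 0.011) or 3 (-1.54, adjusted p = 0.0165) at 6 weeks. Limma called 0 of 13576 probe sets, with 768 at an unadjusted p under 0.05 against 679 by chance, and 1373 (10.1%) did not overlap, where chance gives 10%. Without cellulose replicate 3 at 6 weeks or replicate 2 at 10 weeks 2 probe sets were called, and without replicate 3 at 10 weeks 26. Camera called 7 of 37 lists, 2 higher and 5 lower, and 12 without cellulose replicate 3 at 10 weeks; the estimated correlation and fry called 0, with 5 lists at an unadjusted p under 0.05 in fry. Without replicate 2 at 10 weeks the adjusted p was 0.082 for ER stress, 0.771 for oxidative phosphorylation and 0.525 for proteasome genes. Without replicate 3 at 6 weeks it was 0.217 for oxidative phosphorylation and 0.109 for urea cycle genes, and for proteasome genes it was 0.0829 and 0.0736 without replicates 1 and 2 at 6 weeks. The oxidative phosphorylation mean was -0.06 without replicate 3 at 6 weeks, and -0.04 and -0.18 without replicates 2 and 3 at 10 weeks, and the proteasome mean was -0.06 without replicate 2 at 10 weeks. The actin covariate ended both of these calls. The proteasome call was also lost with the acinar covariate, after quantile normalization, with array weights and on only the arrays compared. It was lost as well without all arrays high in acinar transcripts, garlic arrays among them. On cellulose as on garlic, time could not be told apart from any batch of processing or difference in cages.

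**Figure D4:**
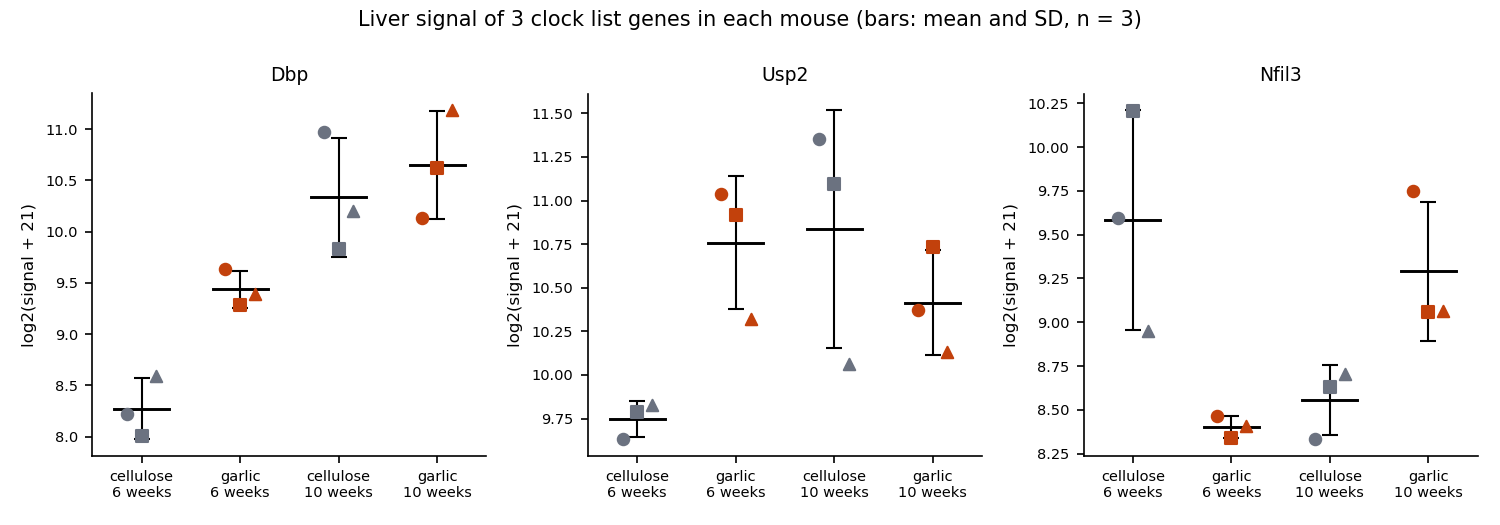
Signal of the clock-linked genes Dbp, Usp2 and Nfil3 in each mouse, as log2(signal + 21), by diet and weeks, with symbols for the replicate number and lines with bars for mean and SD of 3 mice. On cellulose mean Dbp signals were 292.6 at 6 weeks and 1342 at 10 weeks, and on garlic 675.6 and 1655.

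Between 6 and 10 weeks on garlic, again no gene passed. Junb differed by 2.29 ± 0.40 (log2, adjusted p = 0.273), the adaptor gene Sorbs3 by 1.18 and the methyl-CpG binding gene Mbd1 by 0.84 (0.405 for both), and the small heat shock gene Hspb1 by 0.79 (0.442). Lower values at 10 weeks were measured for Ube2g2, a ubiquitin-conjugating enzyme (-1.07 ± 0.21), Slc22a7 (-0.99) and Cd81 (-0.57, adjusted p = 0.405 for the 3), and for Tsc22d3, a glucocorticoid-induced gene (-1.15 ± 0.24), and Selenbp1 (-0.83 ± 0.18, adjusted p = 0.442 for both). Male-biased liver genes, set by the pulses of growth hormone in males, fell in 18 of 19, mean -0.30 (camera, adjusted p = 0.000166; adjusted p = 0.992 with an estimated correlation). Of these, Nat8 (-0.49 ± 0.15), Serpina12 (-0.72 ± 0.22) and Ugt2b1 (-0.61 ± 0.18) passed adjusted over the list alone, against 0 in limma over all genes, where 4 had an unadjusted p under 0.05. Genes of bile acid synthesis and transport fell in 20 of 25, mean -0.18 (adjusted p = 0.0423; adjusted p = 0.992 with an estimated correlation). Of its members 0 passed in limma, adjusted over the list alone or over all genes, and 1 higher and 3 lower had an unadjusted p under 0.05. The acinar list differed by a mean of -0.70 and was not called (adjusted p = 0.278). The mean turned to 0.24 without replicate 2 at 6 weeks and to 0.33 without replicate 1 at 10 weeks, and was -0.23 without replicate 1 at 6 weeks. The list was called without replicate 3 at 6 weeks (-2.10, adjusted p = 7.99e-07) or replicate 2 at 10 weeks (-1.69, adjusted p = 0.000863). Limma called 0 of 13576 probe sets. There were 773 at an unadjusted p under 0.05 against 679 by chance, and 1578 (11.6%) did not overlap, where chance gives 10%. Camera called 2 of 37 lists, and the estimated correlation and fry called 0, with 1 at an unadjusted p under 0.05 in fry. Without garlic replicate 2 at 6 weeks 0 lists were called, with adjusted p = 0.289 for male-biased (mean -0.17) and 0.441 for bile acid genes, and the bile acid call was also lost without garlic replicate 1 (0.268) or 2 (0.066) at 10 weeks. Leaving out the arrays high in acinar transcripts left 1 mouse at each time and ended both list calls. The bile acid call was also lost without a filter, with the upper 40%, after quantile normalization or median centring, and with array weights, the acinar or the actin covariate. Without garlic replicate 2 at 10 weeks 3 probe sets were called.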

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

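The tests of the differences below by fry and by permutation were chosen after the results were seen, and the other tests were not.

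For targets of NRF2 the diet effect was higher at 10 than at 6 weeks by a mean log2 of 0.333 over 35 genes, by a test of the difference itself (camera, adjusted p = 0.0225; adjusted p = 0.908 with an estimated correlation). Phase II conjugation enzymes differed by 0.235 over 30 genes (adjusted p = 0.0181; adjusted p = 0.908 with an estimated correlation). ER stress genes differed by 0.272 over 26 genes (adjusted p = 0.0181; adjusted p = 0.908 with an estimated correlation). Ribosomal protein genes differed the other way, by -0.214 over 27 genes (camera, adjusted p = 0.00201, and 0.908 with an estimated correlation). For phase II, ER stress and ribosomal protein genes the group means moved more between times on cellulose than on garlic. Permutation of the diet labels within times gave unadjusted two-sided p = 0.075, 0.1, 0.35 and 0.165 for NRF2, phase II, ER stress and ribosomal genes. This permutation is not exact for a difference, because an averaged diet effect enters the permuted values and can raise p. Of 100 splits of the mice, 83 gave as many as the 4 lists, and the highest of the others gave 19. These splits moved diet labels within each time, so an averaged diet effect can enter them. They therefore cannot decide on chance for the difference, which is not excluded. Limma called 0 probe sets for the difference, and no split can give fewer, so the 100 of 100 splits with as many (highest other 5) say nothing about chance.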

How the results depend on the processing

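The acinar covariate, the actin covariate, leaving out the 5 arrays high in acinar transcripts, fry, the permutation of list means and all tests of lists for time on garlic were chosen after the results were seen. No count or value below reversed its direction, and where a value moved the cause was not tested. The counts of probe sets called by limma for diet at 6 weeks and averaged, 3 and 4, became 1 and 8 with the offset of 107, 0 and 0 without a filter, 7 and 32 with array weights, 6 and 12 at an adjusted p under 0.10, 1 and 1 with the acinar covariate, and 0 and 0 with the actin covariate and again without the acinar arrays. With the upper 40% the 6-week count was 1. The averaged count was 0 after quantile normalization, 0 after median centring, 1 without a variance trend and 7 with 1 probe set per gene. For time on cellulose array weights gave 12 and the looser threshold 1, against 0. The lists called, 9 at 6 weeks, 10 at 10 weeks, 13 averaged, 4 for the difference, 7 for time on cellulose and 2 for time on garlic, became 0 in each with an estimated correlation and 0 in each with fry. The permutation of list means gave 0 for the averaged effect and 0 for the difference, where an averaged diet effect enters the permuted values. The acinar covariate gave 3 lists at 10 weeks, 7 averaged and 1 for time on garlic, and leaving out the acinar arrays gave 5, 1, 5, 0, 5 and 0 at 6 weeks, at 10 weeks, averaged, for the difference, for time on cellulose and for time on garlic. A model on only the arrays compared gave 5 lists at 10 weeks, and array weights gave 11 for time on cellulose. For time on garlic 1 list was called without a filter, 1 with the upper 40%, 1 after quantile normalization, 1 after median centring and 1 with the actin covariate. The correlation of the diet effects was 0.222 without a filter and 0.217 without the acinar arrays, against 0.371. Leaving out these arrays kept 1 garlic mouse at each time, assumed to vary like the other groups, against 2 cellulose mice at 6 weeks and 3 at 10 weeks, so calls lost there say little about stability. Replicate numbers gave no clear pairing of the mice: 3 of 18 pairs correlated over 0.1, the range was -0.26 to 0.29, and 6 of 12 arrays correlated best with their own number. No chance value was computed for these counts, so a pairing is not excluded. The replicate block gave 0 probe sets in each comparison, and 11, 10, 13, 4, 7 and 2 lists in the order above. Leaving out single arrays gave 0 to 18 probe sets at 6 weeks, 0 to 63 at 10 weeks, 0 to 124 averaged, 0 to 7 for the difference, 0 to 26 for time on cellulose and 0 to 3 for time on garlic, 4 to 16, 5 to 15, 8 to 16, 1 to 10, 6 to 12 and 0 to 3 lists in the same order, and correlations of 0.273 to 0.399. Where an array was left out of a group the other 2 and the spread of all groups carried the test. Of the values of named genes, 1146 kept their side of the threshold, 53 passed it and 49 lost it without single arrays. Under other settings these numbers were 2225, 32 and 52. Most named values were not past the threshold at first, so keeping their side mostly meant staying uncalled. Only called values could lose it. Among these, Alas1 at 6 weeks passed in the largest share of alternatives, 9 of 20, and Tff2 at 6 weeks in the smallest, 5 of 19. The low number of arrays limits what could be detected.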

Other observations

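All tests of acinar, acute phase, macrophage and clock explanations below were chosen after the result was seen. The count of exocrine genes replaced their median correlation with the acinar mean, which had met its threshold but does not apply, because the arrays fall into separate clusters. The splits of the mice were planned beforehand, apart from that for the lists of time on garlic.

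Values of further genes and lists are for the diet effect averaged over both times, with 6 mice per diet, unless a time is given. Tfrc, the transferrin receptor that takes up iron, was at log2 0.72 ± 0.15 (limma, adjusted p = 0.113), and it passed with Alas1 adjusted over the list of 22 iron and heme genes alone, a list that camera did not call (adjusted p = 0.371). Csad, which makes the taurine precursor hypotaurine from cysteine sulfinate, was at 0.84 ± 0.19 and Gys2, liver glycogen synthase, at 0.68 ± 0.15 (adjusted p = 0.132 for both). Among targets of the xenobiotic receptors CAR and PXR, 13 of 21 were higher with a mean of 0.20, which camera did not call (adjusted p = 0.342). Without cellulose replicate 1 at 10 weeks that mean was 0.11, and without cellulose replicate 3 at 10 weeks the list was called (0.28, adjusted p = 0.00459). Adjusted over that list alone 4 passed, among them Cyp2c55 (1.54 ± 0.40) and Ces2a (0.70 ± 0.19), against Alas1, the 1 member past the threshold over all genes. Cholesterol synthesis genes were higher in 16 of 19, mean 0.18, and were not called (adjusted p = 0.0701). At 10 weeks leaving out cellulose replicates 1, 2 and 3 in turn gave averaged means of 0.12, 0.36 and 0.07, with a call without replicate 2 (adjusted p = 3.34e-05). The list was also called without cellulose replicate 2 (0.22, adjusted p = 0.0338) or garlic replicate 3 (0.20, adjusted p = 0.0494) at 6 weeks, or garlic replicate 1 at 10 weeks (0.21, adjusted p = 0.0245). At 6 weeks Abcg5, a sterol exporter, was at 0.76 ± 0.19 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.20 ± 0.35, and both passed adjusted over the bile acid list alone, against 0 in limma over all genes, where 6 were higher and 1 lower at an unadjusted p under 0.05.

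Transcripts of pancreatic acinar cells were high in 5 of 12 arrays, 4 of garlic and 1 of cellulose mice. The garlic diet stays open: 3 garlic arrays had a lower acinar mean than the highest cellulose array, but that rests on this 1 array (10.24), since the next cellulose array (7.48) lay below all 6 garlic arrays. Garlic replicate 3 at 6 weeks (7.66) and replicate 1 at 10 weeks (7.71) lay close to it, however, and outside the 5 high arrays. That order did not hold for Cela2a, with 93 and 238.3 in these garlic arrays against 135.3 in that cellulose array. A candidate explanation is pancreas tissue in the sampled piece. Of 16 exocrine genes outside the acinar list, 12 had their highest signal in those 5 arrays, where chance gives 6.67, and the most abundant, Zg16, Ctrl, Rnase1 and Sycn, reached 4379, 4118, 3474 and 2618 there. The threshold set for this count asked for more than 12 of 16, so it was not met and the count cannot decide. No record of the dissection decides this, so pancreas tissue cannot be told apart from acinar genes active in liver; of the 10 acinar list genes none is on another list, and 4 had means above the median signal in all 4 groups.

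Acute phase genes and macrophage markers were both lower on garlic. With the acinar mean as a covariate the acute phase effect was -0.51 ± 0.388 against -0.804 ± 0.312 without it, and the macrophage effect -0.575 ± 0.441 against -0.617 ± 0.323, so part of the acute phase effect may go with the acinar transcripts. A lower share of all non-parenchymal cells would lower endothelial and stellate markers as well. Endothelial markers differed by 0.03 ± 0.063 over 12 genes (median 0.007, SD 0.244, and -0.008 to 0.076 without single arrays). Stellate markers differed by -0.072 ± 0.091 over 7 genes (median -0.107, SD 0.189, and -0.124 to -0.017 without single arrays). So neither list fell as far as the macrophage list. Macrophage minus endothelial markers was -0.648 ± 0.304 (two-sided exact permutation p = 0.055) and macrophage minus stellate markers -0.545 ± 0.276. The macrophage fall itself had p = 0.075 in the same permutation test. The endothelial and stellate values argue against a fall of all such cells as large as the macrophage mean of -0.617. As the macrophage fall and the gaps are themselves uncertain, a smaller fall in the share of all such cells is not excluded. A change in macrophages alone stays open too. A few inflamed cellulose mice, such as those of 1 cage, could not be excluded either, since the mice of a diet shared cages: the exact permutation p of the acute phase list was 0.277 after adjustment over the lists, 2 of 6 cellulose mice lay within the garlic range, and the cage of each mouse is not in the labels. An effect of garlic itself stays open beside these, and the acute phase list has 5 of its 28 genes on another list.

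From 6 to 10 weeks on cellulose clock genes shifted. The mean of 10 day-phase clock genes, such as Dbp, differed by log2 0.681 ± 0.139 and that of 5 opposite-phase genes, such as Arntl, by -0.538 ± 0.16. Different harvest hours of the groups, which are not in the labels, could give such a pattern. On garlic day-phase minus opposite-phase genes changed by 0.458 ± 0.192, against 1.218 ± 0.192 on cellulose. Among genes past the filter the change on garlic was -0.126 ± 0.22, so the pattern was weaker or absent there. Arntl, below the filter and chosen after its values were seen, had mean signals of 308.7 and 102.7 on cellulose and 133.9 and 77.17 on garlic. A diet effect on the clock at both times would need a like shift at 10 weeks, where day-phase minus opposite-phase genes differed between diets by 0.037 ± 0.192, against 0.797 ± 0.192 at 6 weeks (difference -0.76 ± 0.271). The test was first run on the genes past the filter, 9 day-phase and 2 opposite-phase, and then on all genes, some near the floor. In the first run the shift was 1.049 ± 0.22 at 6 weeks and -0.273 ± 0.22 at 10 weeks (difference -1.321 ± 0.311). The opposite-phase change on cellulose was -0.622 ± 0.169 there. For these genes both runs argue against a like shift at both times, unless hours of death differed between the groups. A smaller shift at 10 weeks stays open. A diet effect at 6 weeks alone cannot be told apart from garlic and cellulose mice having been killed at different hours at that time. The same holds for genes called at 6 weeks, such as Alas1, whose mean signal was lowest in cellulose mice at 6 weeks (6042). In that group day-phase minus opposite-phase values were 1.44, 0.84 and 1.16, and they were 1.87 or more in all other arrays.

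Other splits of the same mice were counted beside each result. For the averaged diet effect 2 of 100 splits, the real one included, gave at least 4 probe sets, and the highest other gave 5. As many calls were thus seldom reached by splits that treat mice as independent. Mice of a diet shared cages, so these splits do not exclude an effect of cages. Chance cannot be excluded for the 13 lists, since 15 of 100 splits gave as many, with 19 as the highest other. For comparisons of 3 against 3 mice there are too few splits, 10, for a share under 0.05. At 6 weeks the real split gave 3 probe sets and the highest other 0, which left 1 of 10 splits as high, and for lists 9 and 14 (5 of 10). Where the real count is 0, as many in each split says nothing. At 10 weeks the values were 0 and 0 for probe sets (10 of 10) and 10 and 16 for lists (4 of 10). For time on cellulose they were 0 and 13 (10 of 10) and 7 and 19 (9 of 10), and for time on garlic 0 and 1 (10 of 10) and 2 and 6 (6 of 10). On cellulose the split that set replicates 1 and 3 at 6 weeks and replicate 3 at 10 weeks against the rest called 13 probe sets, and the split that set replicates 1 and 2 at 6 weeks and replicate 2 at 10 weeks against the rest called 10. The real split called 0 in limma, where 768 had an unadjusted p under 0.05. Such splits, picked after their counts were seen, may point to a structure among these mice, which was not tested further.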
